A study of Nitratidesulfovibrio vulgaris str. Hildenborough with 2 samples.

How the data were processed

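RNA from mid-log cultures of a PerR mutant and of the wild type of the sulfate-reducing bacterium Desulfovibrio vulgaris Hildenborough was measured on 2-colour arrays. Per the labels' protocols, cells grew at 30 °C in defined medium with 68 mM lactate and 28 mM sulfate under an oxygen-free gas stream. cDNA made from 10 ug of total RNA carried Alexa Fluor 647, and genomic DNA of the wild type, the reference on every array, carried Alexa Fluor 555. No dyes were swapped. Each strain has 1 sample entry, which the design text describes as 2 biological samples on 4 arrays with duplicate spots. The columns number the arrays from 1 to 4 and do not name the culture, so arrays could not be averaged by culture.

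Each raw table gives deposited spot intensities of both channels for 6144 spots, of which 472 are controls or blanks that were left out, and 5672 are gene spots of 2825 features. Of the features, 2814 have 2 spots and 11 have 4. Scanner, image software and background method are not given in the sources used here. Most control spots stand at 0 in both tables and no value is negative, so the intensities were taken as background-corrected and floored, and no further background correction was made. Wild-type intensities are whole numbers with a lowest cDNA value of 222 to 753 per array. Mutant intensities have decimals, and no cDNA value lies between 0 and 20982. The tables were thus made in different ways, and each strain lies in a table of its own, so strain and table cannot be told apart in any level set across them. A spot at 0 in cDNA with a genomic DNA signal was read as not above background. On the mutant arrays 819 to 1072 gene spots were of this kind, against 13 to 178 on the wild-type arrays. The reading is doubtful for some of them. They include 2 wild-type spots of DVU3171 and 1 of DVU0775, whose log2 ratios, centred as below, averaged 6.17 and 6.61 in the wild type. A further 31 to 72 spots per array stand at 0 in both channels for a reason the sources used here do not give, many of them in abundant transcripts.

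The authors' deposited comparison lists a log2 ratio of mutant over wild type and a q-value for 2836 rows, with 11 locus tags on 2 rows each, which were averaged. The q-value header, per the file headers, says percent, but the values run from 0 to 0.92 with 1615 rows at the highest, so their scale is not settled and only the entries listed at 0 were used. The authors' value table gives 1 log2 value per gene and strain, with a median of -1.87 for the mutant and -2.07 for the wild type. Set against the mean log2 ratio of cDNA over genomic DNA from the raw tables, these columns correlated across genes at r = 0.999 for the mutant and r = 0.980 for the wild type. That settles the direction. The slope on the raw means was 1.00 for the mutant and 1.13 for the wild type, and the values lay 0.02 and 2.55 above them at the median, so the scale and centring of the wild-type column remain unknown.

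For each spot with both channels above 0, log2 of cDNA over genomic DNA was taken, and spots of a feature were averaged. Each array was centred on its median over the 2272 features measured on all 8 arrays. The plan fixed before the data were examined said only that each array is centred on its median log ratio. The common features were chosen after seeing that the mutant arrays lack many dim features, and the median over all features of each array was run as an alternative. Features measured on at least 2 arrays of each strain were tested, 2444 in all, and 381 were not. limma 3.58.1 (lmFit and eBayes, R 4.3.3) compared the strains with each array as a column, with Benjamini-Hochberg adjustment and a threshold of 0.05. Arrays of 1 culture are technical repeats, so every p-value and adjusted p from this fit, those of gene lists included, is too small. As a bound, the arrays of each strain were also averaged into 2 cultures in all 49 ways that 4 and 4 arrays allow, and the fit was repeated for each. The text gives how many of these 49 assignments called a gene. Gene lists, fixed by locus tag or annotation text before the data were examined, were tested with camera at its preset correlation, with an estimated correlation, and with fry. These tests used features measured on all 8 arrays, and list members were also counted after adjustment over the list alone.

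The named genes were fixed by rule: all measured members of the predicted PerR regulon, the 10 largest increases and 10 largest decreases among called genes without overlap between the strains' arrays, the 3 largest absolute changes in each list, and locus tags within 5 of perR. Genes named outside it are said to have been chosen after their values were seen. Names come from the files and from a RefSeq gene table of assembly ASM19575v1, which matched 2771 of the 2825 features. No genome build is given in the sources used here, so no coordinates are printed. The names perR, rbr2 and ahpC are those of the list fixed beforehand. Fold changes are mutant over wild type, on the log2 scale, with standard errors from the fit, and SDs are over arrays.

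The fit was tested on simulated data with the real arrays' spread: of 100 genes changed by 1 log2 unit it recovered 78.0%, of 100 changed by 2 units 99.0%, and 3.80% of its calls were unchanged genes. With arrays averaged into 2 cultures the shares recovered were 75.0% and 99.0%. Each simulated array was drawn independently, without a culture or table effect, so all these shares hold for independent arrays only. Alternatives covered loess, quantile normalization, the cDNA channel alone, scaling by summed channels, another centring, dim and bright spots, a plain test per gene, a block on array number, stricter thresholds, the PerR list without perR and each array left out in turn. The plan kept loess as an alternative only, since with a genomic DNA reference it would remove expression itself. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The number of arrays and cultures limits the precision of every value.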

Results

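Transcript levels were compared between Desulfovibrio vulgaris Hildenborough, an anaerobic sulfate reducer, and a strain with a mutation in PerR, a repressor of the Fur family that responds to peroxide in other bacteria. The labels do not say what kind of mutation it is. Cells of both strains were in mid-log growth on lactate without oxygen, and the comparison asks which transcripts differ when PerR is altered. Each strain was measured on 4 arrays from 2 cultures. The 4 mutant arrays measured 2354 to 2475 features each and the 4 wild-type arrays 2804 to 2822. Median cDNA intensity was 101461 to 126549 on the mutant arrays and 22444 to 50454.5 on the wild-type arrays. Duplicate spots correlated at r = 0.981 to 0.989. Centred log ratios correlated across genes, which are not independent replicates, at r = 0.949 to 0.990 between mutant arrays, 0.959 to 0.986 between wild-type arrays and 0.855 to 0.904 between the strains. For the genomic DNA channel r was 0.704 to 0.930 between mutant arrays, 0.509 to 0.849 between wild-type arrays and 0.241 to 0.669 between the strains. The reference signal in every ratio thus also differed between the strains' tables.

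The transcript of the mutated gene itself was lower in the mutant. perR (DVU3095) had a log2 ratio over genomic DNA of -1.71 ± 0.06 (SD, n = 4 arrays) in the mutant and 4.66 ± 0.13 (SD, n = 4 arrays) in the wild type. The log2 fold change was -6.38 ± 0.13 (SE), with an adjusted p of 1.98e-11, and all 49 assignments of arrays to cultures called it. In the mutant, 3 of its 8 spots were not above background, and the value was -6.47 with these set to the lowest cDNA signal. The authors' deposited table gives -3.68 with a q-value of 0. After loess the value was -0.46 and no longer passed (adjusted p = 0.082).

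The other predicted PerR targets, apart from the hypothetical gene DVU0772 genes for peroxide and oxygen protection in Desulfovibrio, did not move in a common direction. rdl (DVU3093), which encodes a rubredoxin-like protein, fell by 2.42 ± 0.21 (SE) on the log2 scale. ahpC (DVU2247), an antioxidant protein of the AhpC/Tsa family, rose by 2.07 ± 0.21 (SE), from only 2 mutant arrays, since 4 of its 8 mutant spots stood at 0 in both channels. These turned to 0.52 and -0.45 after loess. DVU0772, of unknown function, had a log2 fold change of -1.20 ± 0.38 (SE, adjusted p = 0.026). That call was lost on leaving out mutant array 1, 2 or 3 or wild-type array 1, 3 or 4, with adjusted p between 0.053 and 0.084, and after loess the value was 0.56. On mutant array 4 its log2 ratio was 4.79, against 2.59 to 3.21 on the other mutant arrays and 4.20 to 4.97 on the wild-type arrays. The rubrerythrin gene rbr (DVU3094) did not pass, at -0.52 ± 0.36 (SE, adjusted p = 0.271), but it passed at -0.89 without wild-type array 2 (adjusted p = 0.026), at -1.27 after loess (adjusted p = 0.018) and in 10 of the 49 assignments. The second rubrerythrin gene rbr2 (DVU2318) could not be tested, as all 8 of its mutant spots stood at 0 in both channels. With perR counted, 1 of 5 tested members was higher and 3 were lower, the same counts as adjusted over the list alone. camera used the 4 members measured on all arrays, with perR and without ahpC, and called them lower, with an adjusted p of 0.0089, and 0.265 with an estimated correlation. Without perR the remaining 3 did not pass (adjusted p = 0.087). The list's median was -1.20, and -0.45 after loess, where no member was higher and 1 was lower. After loess the adjusted p was 0.964 and in the cDNA channel alone 0.054, and 27 of the 49 assignments called it. The authors' deposited table gives 3.31 for ahpC, 2.94 for DVU0772 and -4.16 for rbr2, each at a q-value of 0, and 1.29 for rbr and 0.88 for rdl, neither at a q-value of 0. Of these, rdl, rbr and DVU0772 had the opposite sign in the fit.

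**Figure D1:**
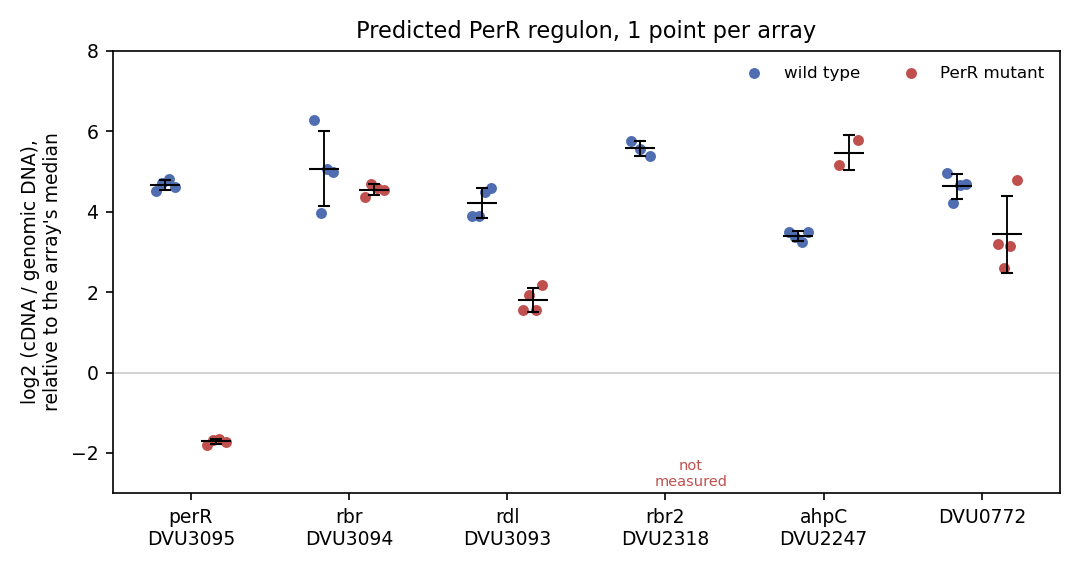
Log2 of cDNA over genomic DNA relative to the array's median (y axis, log2 units) for the 6 genes of the predicted PerR regulon (x axis), with 1 point per array, blue for wild type and red for the PerR mutant; horizontal bars are means and error bars SDs over arrays. The mutant points of perR lie near -1.71 and the wild-type points near 4.66, while those of rbr overlap and rbr2 was not measured in the mutant.

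Among the genes next to perR, rdl and rbr are given above, with rdl lower and rbr not passing, and 2 others were higher. The conserved hypothetical gene DVU3091 rose by 0.68 ± 0.13 (SE) and tolQ (DVU3099), part of the Tol system of the cell envelope, by 0.99 ± 0.22 (SE), with 42 and 43 of the 49 assignments calling them. DVU3091 was at -0.50 after loess. DVU3090, an outer membrane protein, was at 0.28, the efflux protein gene DVU3097 at -0.29 and tolR (DVU3100) at 0.30, and none of these passed, although DVU3097 did without mutant array 4 (-0.34, adjusted p = 0.038), after quantile normalization (-0.59), under the other centring (-0.56) and in a plain test per gene. tolR passed as higher after loess (1.04, adjusted p = 0.0068) and as lower in the cDNA channel alone (-0.98, adjusted p = 0.0051). DVU3092 was not above background on any mutant array.

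Across the genome, 1005 of 2444 tested features passed the threshold, 521 higher and 484 lower in the mutant. Of these, 340 changed at least 2-fold, 156 higher and 184 lower. Centring on all features measured on each array instead gave 264 higher and 813 lower, quantile normalization 254 and 964, the cDNA channel alone 248 and 790, and loess 169 and 287. These settings moved the median of all tested features from 0.04 to -0.23, -0.32, -0.32 and -0.10. The other centring, quantile normalization and the cDNA channel alone set levels over the features each array measured, and mutant arrays lacked many dim ones. On wild-type arrays the median log2 ratio was -4.91 to -4.46 over all measured features and -4.50 to -4.15 over the common ones. On mutant arrays these were -1.92 to -1.70 and -1.83 to -1.54. Centring on all features thus set the wild type higher relative to the mutant. In the other direction, setting cDNA spots at 0 to the lowest signal gave 663 higher and 456 lower of 2812 tested features, with a median of 0.14. That signal was at least 20982 on mutant arrays and 222 to 753 on wild-type arrays, so the setting itself puts spots at 0 lower in the wild type. Scaling by summed channels gave 496 and 423, with a median of 0.07, so the balance of higher against lower genes was not settled. Loess turned the sign of 29 of the 69 named genes that were tested. The p-values behind the counts are too small, as arrays share cultures. Over the 49 assignments the number called ran from 249 to 1224, and 197 genes, 119 higher and 78 lower, were called in all of them. The assignments that set mutant array 4 alone as a culture called 249 to 394, and all others called 635 to 1224.

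The 10 largest increases were in 5 flagellar genes, the secretin gene pilQ with 2 hypothetical neighbours, and 2 hydrogenase genes. The flagellin genes DVU2444, DVU2082 and DVU1441, for the filament protein, rose by 4.75 ± 0.19, 4.04 ± 0.14 and 2.98 ± 0.16 (SE). The hook protein gene flgE (DVU1443) and the hook-length control gene DVU1445 rose by 2.87 and 2.99. pilQ (DVU1273), of the family of secretins that form outer membrane pores, rose by 3.59 ± 0.20 (SE), with its neighbours DVU1274 and DVU1275 at 2.60 and 3.05. The hydrogenase genes DVU2288 (CooL subunit) and cooF (DVU2293) rose by 3.02 and 2.74. The highest adjusted p among these 10 genes was 1.3e-06, and all 49 assignments called each. In the authors' deposited table the 10 had ratios from 1.92 to 4.53, each at a q-value of 0. After loess DVU1273, DVU1275, DVU1441 and DVU2293 turned below 0, and DVU2293 passed there at -2.07 (adjusted p = 0.012).

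Among the decreases, the lactate permease gene DVU2451, for a carrier of the carbon source, fell by 3.98 ± 0.23 (SE). DVU0303 and DVU0304, hypothetical genes counted with the Fur regulon, had log2 fold changes of -3.18 ± 0.13 and -2.91 ± 0.26 (SE). The solute-binding protein gene DVU2615 was at -3.14, and the hypothetical genes DVU0821, DVU2701 and DVU1704 were at -3.39, -3.12 and -2.83. DVU0821 and DVU2701 were measured on 3 mutant arrays, with 4 and 5 of 8 mutant spots not above background, and DVU2701 was at -2.17 with such spots set to the lowest signal. The hypothetical gene DVU2676 had 6 of its 8 mutant spots not above background. It was at -4.24 from the spots left on 2 mutant arrays and at -4.20 with the others set to the lowest signal, so its size and rank are uncertain. On mutant array 4 the ratio of DVU1704 was 2.07, against a median of -0.38 on the other 3. DVU0404, annotated as a dissimilatory sulfite reductase subunit, fell by 2.80 ± 0.42 (SE), with mutant array 4 at 4.79 against 2.56 to 3.11 on the other mutant arrays. All 49 assignments called DVU2451, DVU0303, DVU0304 and DVU2615, while DVU1704 was called in 43, DVU0404 in 46. DVU0821 and DVU2701 were called in each of the 42 assignments that could test them and DVU2676 in each of 28. After loess DVU2676 and DVU0821 were at -0.95 and -0.52 and did not pass. The authors' deposited table gives 3.11 for DVU0404 at a q-value of 0, and 1.22 for DVU1704, not at a q-value of 0. DVU0303 and DVU1704 turned above 0 after loess, and DVU1704 passed there at 0.79 (adjusted p = 0.019).

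The flagella and chemotaxis list moved up, with 40 of 87 tested members higher, 22 lower and 25 not passing (41 and 23 adjusted over the list alone). camera gave an adjusted p of 0.030 and 0.265 with an estimated correlation, and the call was lost without mutant array 4 (adjusted p = 0.084), after loess (0.148) and with cDNA spots at 0 set to the lowest signal (0.161). Of the 18 lists tested 4 were called, but 5 of the 35 divisions of the 8 arrays into 4 and 4, the real one included, called at least 4. The others of these 5 kept 3 mutant arrays together and so still held part of the strain contrast. The flagella list's median was 0.28, and -0.10 after quantile normalization, with 32 members higher and 32 lower. A division by annotation, made after the values were seen, separated the members. Of 39 flagellar genes, 35 were higher and 2 lower, with a median of 1.41. After loess 11 were higher and 1 lower, 14 lay below 0 and the median was 0.24. Of 22 methyl-accepting chemotaxis proteins, sensors of the chemotaxis system, 3 were higher and 8 lower, and of 26 other chemotaxis genes 2 were higher and 12 lower. After loess these counts were 1 and 3 for the sensors and 4 and 4 for the other genes, with medians of -0.41 and -0.02, and after quantile normalization 2 and 14, and 0 and 15. The difference between these parts was not tested.

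Hydrogenases, which produce or take up hydrogen, moved in opposite directions, with 9 of 20 tested members higher and 9 lower, as also adjusted over the list alone, and no shift as a list (adjusted p = 0.910). All 8 genes of the Coo cluster (DVU2286 to DVU2293) were higher, by 1.54 to 3.02. The Ech hydrogenase (DVU0429 to DVU0434), was lower in all 6 genes, from -2.74 for DVU0429 to -2.01. All 14 were called under all 49 assignments, but after loess 7 Coo genes lay below 0 and 2 Ech genes above. After quantile normalization, under the other centring, with summed-channel scaling and in the cDNA channel alone, all 8 Coo genes were called higher. The 6 Ech genes were all called lower in each of these. The division into these clusters was made after the values were seen. The second periplasmic [NiFe] hydrogenase genes hynB-2 (DVU2525) and hynA-2 (DVU2526), also chosen after the values were seen, were not above background on any mutant array and at least 2.78-fold and 2.27-fold lower there. Such bounds set the wild-type mean against the lowest cDNA signal of each mutant array, so they depend on the level set between the strains' tables. The authors' deposited table gives -0.26 for hynB-2 and -0.39 for hynA-2, neither at a q-value of 0.

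The iron uptake and Fur-related list was lower, with 8 of 13 members lower, 1 higher and 4 not passing, as also adjusted over the list alone, and a median of -1.22 (-0.05 after loess, with 1 higher and 1 lower). Its adjusted p was 0.030, and 0.353 with an estimated correlation. The call was lost without mutant array 3 (adjusted p = 0.064) or wild-type array 2 (adjusted p = 0.057), after loess (0.964) or quantile normalization (0.062), under the other centring (0.085) and in the cDNA channel alone (0.054). DVU0303 and DVU0304 led it, followed by the bacterioferritin gene bfr (DVU1397), for an iron storage protein, at -2.25 ± 0.47 (SE), with mutant array 4 at 1.63 against a median of -0.75 on the other 3, and it was 0.24 after loess. The ferrous iron transporter gene feoB (DVU2571), named after its value was seen, was higher at 0.84, a call lost after loess and under the other centring (0.57). Of the 4 Feo genes 1 was higher, 1 lower and 2 did not pass, with a median of -0.26. The zinc list had 2 of 4 members higher and none lower (3 adjusted over the list alone; camera adjusted p = 0.087), and 1 higher after loess, quantile normalization or the other centring. Its largest values were 1.17 ± 0.13 (SE) for the binding protein gene DVU1343 (-1.77 at a q-value of 0 in the authors' deposited table), 0.55 for the permease gene DVU1341 and 0.38 for the regulator gene DVU1340. The last did not pass, but did without wild-type array 3 (0.48, adjusted p = 0.039) and in 3 of the 49 assignments.

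Of 21 tested genes for oxygen and peroxide defence outside the PerR list, 2 were higher and 8 lower (2 and 9 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.055). It passed as lower with array number as a block (adjusted p = 0.042), without mutant array 2 (0.049) or wild-type array 3 (0.047), with cDNA spots at 0 set to the lowest signal (0.041), without the brightest spots (0.027) and in 6 of the 49 assignments. With an estimated correlation the adjusted p was 0.265. After loess 1 member was higher and 1 lower, and after quantile normalization 2 and 14. The cytochrome bd oxidase genes cydA (DVU3271) and cydB (DVU3270), for a membrane oxygen reductase, rose by 1.57 ± 0.26 and 1.49 ± 0.23 (SE), but cydA was at 0.64 in the cDNA channel alone and did not pass (adjusted p = 0.109), and cydB was at -0.26 after loess. The 5 listed genes of the cytochrome c oxidase cluster (DVU1811 to DVU1815) were lower, from -1.30 to -0.69. They lay below 0 under each other scaling, but 1 of the 5 was called after loess, and none was called in all 49 assignments. The rubredoxin gene rd (DVU3184), for a small electron carrier, fell by 2.57 ± 0.44 (SE), with mutant array 4 apart from the others.

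**Figure D2:**
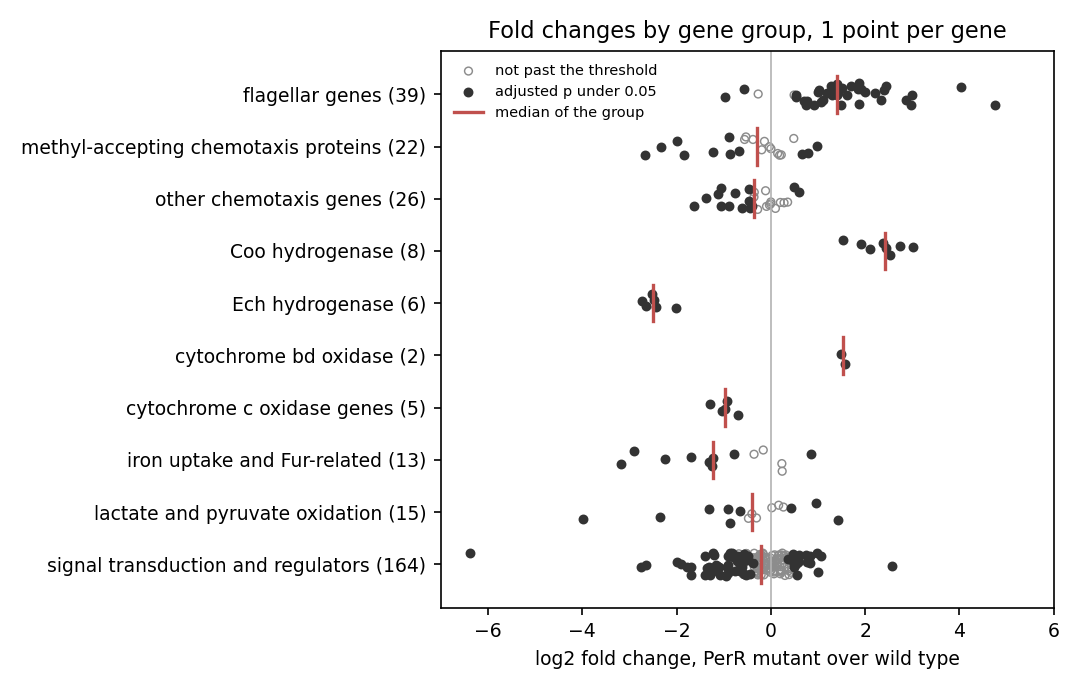
Log2 fold change of the PerR mutant over wild type (x axis) for the genes of 10 groups (y axis, number of tested genes in brackets), with 1 point per gene, filled where the adjusted p was under 0.05 and open where not, and a red line at the median. Flagellar and Coo genes lie mostly above 0, with medians of 1.41 and 2.41, and Ech genes near -2.51; after loess most Coo genes lay below 0 and the flagellar median was 0.24.

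In energy metabolism, lactate and pyruvate oxidation had 3 of 15 tested members higher and 6 lower, as also adjusted over the list alone (camera adjusted p = 0.087). After loess 1 was higher and 1 lower, and the list passed as lower without the brightest spots (adjusted p = 0.027). Besides DVU2451, the lactate permease gene DVU3026 fell by 2.35 ± 0.20 (SE), and nifJ (DVU3025), for pyruvate-ferredoxin oxidoreductase, rose by 1.43 ± 0.20 (SE). These were 0.31 and -0.90 after loess, where nifJ passed as lower (adjusted p = 0.047). Sulfate reduction had 1 of 10 tested members higher and 3 lower (1 and 5 adjusted over the list alone; camera adjusted p = 0.139), and 7 members were not tested. After loess 2 were higher and 1 lower, and under the other centring 0 and 6. Here DVU0849, a heterodisulfide reductase subunit gene, was at 0.68 and dsrP (DVU1286) at -0.61, and leaving out single arrays lost either call, DVU0849 without mutant array 2 or 3 or wild-type array 1, 2 or 4 (adjusted p up to 0.098) and DVU1286 without mutant array 1, 3 or 4 or wild-type array 1, 2 or 4 (up to 0.117). Among formate dehydrogenases 3 of 5 tested members were lower and none higher (also over the list alone; camera adjusted p = 0.087), and none passed after loess. With cDNA spots at 0 set to the lowest signal 1 of 7 was higher and 2 lower. The 3 lower members were DVU2481 at -1.09, fdnG (DVU0587) at -1.08 and the cytochrome gene DVU2483 at -0.65, of which the first pair turned above 0 after loess.

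Of 19 tested members of membrane electron transfer complexes and cytochromes, 5 were higher and 3 lower, as also adjusted over the list alone (camera adjusted p = 0.139). After loess 0 were higher and 3 lower, and after quantile normalization 5 and 5. tmcC (DVU0265) rose by 1.24 ± 0.31 and DVU2793, an RnfD subunit gene, by 1.15 ± 0.17 (SE), but after loess tmcC passed as lower, at -1.53 (adjusted p = 0.0052). The cytochrome c3 gene DVU3171 was at -1.14 ± 0.30 (SE), a call lost without wild-type array 3 or 4 (adjusted p = 0.051 and 0.053) and turned to 3.17 with cDNA spots at 0 set to the lowest signal. That setting lowered 2 of its wild-type spots, although its wild-type mean was 6.17. The authors' deposited table gives 2.68 for DVU3171 at a q-value of 0. ATP synthase had 1 of 9 members lower, also over the list alone (camera adjusted p = 0.315), DVU0780 at -1.01, and 4 lower under the other centring. atpC (DVU0774) at -0.44 and atpD (DVU0775) at -0.31 did not pass, although atpC did in 5 of the 49 assignments and atpD after loess (-1.09, adjusted p = 0.033) and under the other centring (-0.59, adjusted p = 0.030).

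The list of signal transduction proteins and transcription regulators was lower, with 20 of 164 tested members higher and 49 lower, as also adjusted over the list alone, and a median of -0.20. After loess 10 were higher and 21 lower, with a median of -0.16, and after quantile normalization 5 and 94. Its adjusted p was 0.030, and 0.265 with an estimated correlation, and the call was lost without mutant array 3 (adjusted p = 0.064), after loess (0.964) and in the cDNA channel alone (0.054). After perR, large changes were in the histidine kinase genes DVU2616, at -2.75 from 2 mutant arrays with 5 of 8 mutant spots not above background, and DVU2281, at -2.65 ± 0.16 (SE).

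Ribosomal proteins had 6 of 56 members higher and 15 lower (5 and 13 adjusted over the list alone; camera adjusted p = 0.087), and 0 and 11 after loess and 1 and 23 under the other centring. The list passed as lower with cDNA spots at 0 set to the lowest signal (adjusted p = 0.041). rpsU (DVU1792) was at -2.65 ± 0.48, with mutant array 4 apart from the others, rpmE (DVU2912) at -1.73 ± 0.26 and rpsJ (DVU1302) at -1.42 ± 0.16 (SE). The authors' deposited table gives 2.52 for rpsU and 1.54 for rpmE, each at a q-value of 0. Of 25 tRNA synthetases 6 were higher and 3 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.910), but 1 and 10 after quantile normalization and under the other centring and 1 and 9 in the cDNA channel alone. valS (DVU0732) was at 0.68. argS (DVU1248) at -0.66 was lost without mutant array 2 or 3 or wild-type array 3 or 4 (adjusted p up to 0.091), and thrS (DVU2538) at 0.64 without mutant array 1, 2 or 3 or wild-type array 3 (up to 0.060). Of 15 chaperones and heat shock proteases 3 were higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.598), but 1 and 8 after quantile normalization, 0 and 7 under the other centring, 1 and 6 in the cDNA channel alone and 0 and 2 after loess. ftsH (DVU1278) was at -0.96 and lost without mutant array 2 (adjusted p = 0.051), dnaK (DVU0811) at 0.71 and lost without mutant array 2 or 3 (0.055 and 0.051), and groL (DVU1976) at 0.64 and lost without mutant array 2 or 3 or wild-type array 1, 3 or 4 (up to 0.088).

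Among ABC transporters, 19 of 105 tested members were higher and 18 lower (17 and 18 adjusted over the list alone; camera adjusted p = 0.910), but 5 and 38 after quantile normalization, 6 and 33 in the cDNA channel alone, 5 and 29 under the other centring and 9 and 13 after loess. The peptide-binding protein gene DVU0169 fell by 1.74 ± 0.16 and the ATP-binding protein gene DVU1049 rose by 1.44 ± 0.16 (SE), and DVU0169 was 0.62 after loess. Prophage-annotated genes had 4 of 11 tested members higher and 1 lower, also over the list alone (camera adjusted p = 0.194), and 13 were not tested. The counts were 1 and 4 after quantile normalization, 0 and 2 after loess, 1 and 2 under the other centring, 1 and 3 in the cDNA channel alone, and 9 and 1 of 24 with cDNA spots at 0 set to the lowest signal. The phage shock gene pspA (DVU2988), an envelope stress gene and not a prophage gene, rose by 0.89, the integrase gene DVU1757 was at -0.99 with 5 of 8 mutant spots not above background, and DVU0197 at 0.82, from 2 mutant arrays, did not pass. It passed without wild-type array 3 (1.03, adjusted p = 0.018), with summed-channel scaling, with spots at 0 set to the lowest signal, with a block on array number and in 20 of the 28 assignments that could test it. The nitrogen fixation list had 3 of 7 tested members higher and 2 lower, also over the list alone (camera adjusted p = 0.597), with none passing after loess and 2 and 2 after quantile normalization. Its text match brought in hydrogenase genes, so the counts are not of nitrogen fixation genes alone. Among them were the [NiFeSe] hydrogenase genes hysB (DVU1917), at 1.29, and hysA (DVU1918), at -0.77, the latter lost without mutant array 2 (adjusted p = 0.054). The [NiFe] hydrogenase genes hynB-2 and hynA-2 were matched too and could not be tested. nifU (DVU0665) was at 0.74. The only type III secretion gene on the array, the chaperone gene DVU2392, was at -0.44, lost without mutant array 1 or 2 or wild-type array 1, 2 or 4 (adjusted p up to 0.098). The lists of plasmid and CRISPR-associated genes had no members on the array.

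The authors' deposited table lists 263 rows at a q-value of 0, 125 with a higher and 138 with a lower ratio in the mutant. In it, 10 of 13 iron uptake and Fur-related members were lower at a q-value of 0, with the Feo transporter genes from -4.87 to -3.55 and the flavodoxin gene DVU2680 at -5.87. A two-sided Fisher's exact test against the other genes of the authors' deposited table gave an adjusted p of 5.39e-10, treating genes of an operon as independent. All 8 Coo genes were higher at a q-value of 0, by 3.28 to 4.53, and 15 of 56 ribosomal protein genes were higher (adjusted p = 9.34e-08). Over the 38 such tests, hydrogenases (adjusted p = 7.29e-09), flagella and chemotaxis (0.021) and sulfate reduction (0.030) also had more higher genes. Oxygen and peroxide defence (0.021), formate dehydrogenases (0.022) and lactate and pyruvate oxidation (0.030) had more lower genes, and ABC transporters (0.038) fewer higher genes. The deposited ratio and the fitted fold change correlated across 2442 genes, which are not independent, at r = 0.384 and rho = 0.276. Of 252 tested genes at a q-value of 0, 166 were called in the fit, against 103.6 for independent lists. Of these, 141 had the same sign, 56 higher and 85 lower in both, and 25 did not. For feoB (DVU2571) the authors' deposited table gives -4.87 and the fit 0.84. The difference of the authors' own value columns correlated with the fit at r = 0.941 and with their deposited ratio at r = 0.321.

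**Figure D3:**
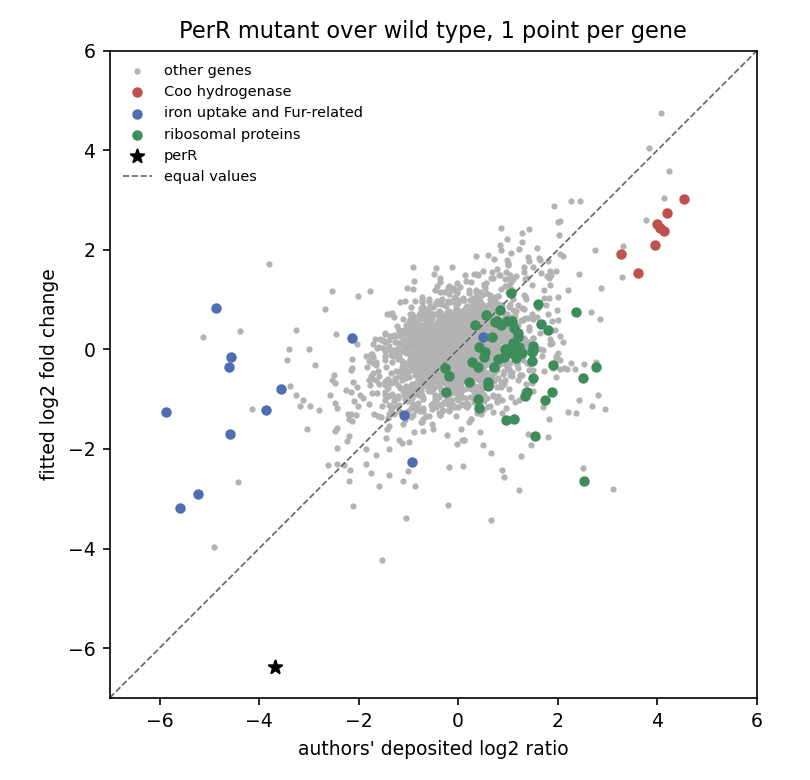
Fitted log2 fold change (y axis) against the authors' deposited log2 ratio (x axis), mutant over wild type, with 1 point per gene, Coo genes in red, iron genes in blue, ribosomal protein genes in green, perR as a star and a dashed line of equal values. Across 2442 genes r was 0.384; Coo genes were high in both, and most iron genes lay lower in the deposited ratio than in the fit. After loess 7 of the 8 Coo genes lay below 0 in the fit.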

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

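The tests of locus tags, of other wild-type arrays, of the scalings without loess, of the gene list count and of mutant array 4 were chosen after the results were seen. In 10 of 143 sets of 4 arrays, 1 array stood far from the other 3. Chance alone gives this in about 1 set in 20. The number given is the gap to the nearest array divided by the whole range. Mutant array 4 was the outlying array in 5 sets: flgE DVU1443 (0.9004), DVU1704 (0.855), the rubredoxin gene DVU3184 (0.9204), the bacterioferritin gene DVU1397 (0.884) and rpsU DVU1792 (0.905). Wild-type array 2 was so in 3: the flagellin gene DVU1441 (0.882), DVU1704 (0.895) and nifJ DVU3025 (0.976). Mutant array 1 stood apart for DVU2483 (0.833) and wild-type array 3 for DVU0169 (0.955).

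Mutant array 4 stood higher than the other mutant arrays in all 5 genes. The number of measured features argues against a loss of spots, as it measured 2400, inside the 2354 to 2475 of the others. Its median cDNA intensity was the lowest, 101461 against 104383 to 126549, so by this test brightness stays open. Array 2, at 126549, lay further from arrays 1 and 3, at 106280 and 104383, than array 4 did. Array 2 still correlated with them at 0.982 and 0.986, so a gap of that size did not set it apart. An origin of array 4 in the other culture may explain the difference, and stays open: its highest correlation with another mutant array was 0.957 and the lowest among the other 3 was 0.982, but the columns do not name the culture. Array 4 also correlated more with the wild-type arrays, at 0.896 to 0.904, than the other mutant arrays did, at 0.855 to 0.891. With array 4 taken as a culture of its own, 249 to 394 genes were called, against 1005 in the fit by arrays. A difference between cultures of 1 strain would be biological or technical, and was not tested.

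The counts of genes and of gene lists were set against chance. Of the 35 ways to divide the 8 arrays into 4 and 4, only 1, the real one, called as many as its 1005 genes, and the highest other count was 0. Every other division put arrays of both strains in each group, so the strain difference widened the spread within groups. A count of 0 there thus gives no chance level for the 1005 genes. Of the same 35, 5 called at least as many lists as the real 4, and the highest other count was 6. The other divisions among these kept 3 mutant arrays together and so still held part of the strain contrast. Divisions with 2 mutant arrays on each side called at most 3 lists. Such divisions balance the strains, so these lists were called without the strain contrast. The strain difference then lay within the groups, so their counts are no clean chance level. Chance is not excluded for the lists. Arrays share cultures, and 4 cultures divide into 2 and 2 in only 3 ways, too few for a share under 0.05. Neither count separates the mutation from the raw table, the culture or the scan, which change with the strain.

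The deposited ratios and the fitted fold changes disagreed across genes (r = 0.384). Normalization was argued against, as no alternative fit raised r above 0.441. Saturated or undetected spots were too, since over 1181 genes with every spot measured and in the middle of the signal range r was 0.377. Wrong locus tags in the raw tables were argued against by neighbouring genes, whose fitted fold changes correlated at 0.337, above the highest of the shuffled orders at 0.062. That the deposited ratios rest on other wild-type arrays may still explain it: the wild-type level implied by mutant level and deposited ratio correlated with the measured one at 0.833. The mutant level implied in the same way correlated at 0.899 with the measured one, so these values do not point to the wild-type arrays in particular, and arrays not used here cannot be compared.

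The 10 largest increases were tested for technical sources. The genomic DNA channel was argued against, as the lowest of the 10 was 2.02 in the cDNA channel alone. For scaling, the test written before the result counted loess among 4 other scalings, and by that test scaling may account for the increases: the lowest of the 10 was -2.07, under loess. With loess left out, a test chosen after that outcome was seen, the lowest was 2.33. Log ratio and brightness correlated at 0.817 to 0.858 within arrays, the trend that loess removes. The SD of log2 cDNA signal within arrays was 1.79 to 1.83 on mutant arrays and 2.08 to 2.21 on wild-type arrays. For genomic DNA it was 0.52 to 0.54 and 0.64 to 0.78, so brightness mostly followed the cDNA. Both spreads were smaller on the mutant arrays, and the reason was not tested. The plan said beforehand that loess would remove expression itself, and perR went to -0.46 there. Loess thus cannot tell a scaling error from a change in expression. The outcome of the test stands, and scaling stays open. All 10 were called in each of the 49 assignments, and a difference between tables or cultures other than the mutation cannot be told apart from it, since each strain lies in its own table.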

How the results depend on the processing

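Centring on all features of an array, the treatment of cDNA spots at 0, summed-channel scaling, the bright-spot filter, the PerR list without perR and the culture assignments were chosen after seeing the data. The 1005 genes called became 456 after loess, 614 at an adjusted p under 0.01, 340 at 2-fold or more, and 249 under the lowest of the 49 assignments of arrays to cultures, and ran from 772 to 1156 with each array left out. The assignment that called 249 set mutant array 4 alone as a culture. perR was -0.46 after loess and no longer passed, and otherwise kept its call, from -6.42 to -6.32 with each array left out. The 4 lists called became 0 after loess, 1 in the cDNA channel alone, 0 with an estimated correlation, 12 with fry, 0 under the lowest assignment, 3 with perR left out of the PerR list, and 2 to 5 with each array left out. At an unadjusted p under 0.05, camera called 3 lists after loess and, with an estimated correlation, only the PerR list (p = 0.015). The correlation with the deposited ratio became 0.063 after loess and was 0.349 to 0.404 with each array left out. Over 69 named genes and 1208 gene and setting pairs, 1057 kept direction and call, 93 lost the call, 14 gained it and 44 changed sign. After loess these were DVU1273 -0.86, DVU1275 -0.44, DVU1441 -0.24, DVU2293 -2.07, DVU0303 0.14, DVU1704 0.79, DVU3093 0.52, DVU2247 -0.45, DVU0772 0.56, DVU3090 -0.072, DVU3091 -0.50, DVU3270 -0.26, DVU1397 0.24, DVU1340 -0.37, DVU0849 -0.47, DVU3026 0.31, DVU3025 -0.90, DVU0429 0.30, DVU2481 0.34, DVU0587 0.16, DVU0265 -1.53, DVU0780 0.14, DVU1278 0.65, DVU1976 -0.34, DVU2988 -0.020, DVU1917 -0.65, DVU0732 -0.0023, DVU2538 -0.81 and DVU0169 0.62, of which DVU2293, DVU1704, DVU3025 and DVU0265 passed in the new direction. The iron list turned with an adjusted p of 0.964. Loess removes the tie of log ratio to brightness (r = 0.817 to 0.858 within arrays). With a genomic DNA reference that tie holds expression itself, as the plan said beforehand. In the cDNA channel alone DVU3094 was 0.13, DVU3090 -0.15, DVU3100 -0.98, DVU1341 -0.11, DVU3171 0.15, DVU0775 0.011 and DVU0197 -0.045. After quantile normalization DVU3090 was -0.11, DVU0775 0.010 and DVU0197 -0.048. With cDNA spots at 0 set to the lowest signal DVU3097 was 0.24, DVU2483 0.32, DVU3171 3.17, DVU0775 1.48 and DVU2392 0.082. Each of these genes had wild-type spots at 0 in cDNA. The setting put those spots at 222 to 753, which lowers the wild-type mean. For the cDNA channel alone, quantile normalization and loess the cause was not tested. With array number as a block 1016 genes and 5 lists were called, but same-numbered arrays deviated together at r = 0.07, 0.10, -0.19 and 0.19, so the numbers do not pair the arrays. Other background corrections and offsets were not run, as the intensities were taken as background-corrected, which was not tested. On the wild-type arrays 6 to 82 of 472 control spots were above 0 in cDNA. A random block on the culture was not run either, as the columns do not name it. Dim transcripts are limited by the mutant table, where no cDNA signal lies between 0 and 20982.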

Other observations

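All groups in this part were chosen after the values were seen. Runs of at least 6 neighbouring tested genes, all called and all in 1 direction, numbered 10, of which 7 were higher and 3 lower in the mutant. Under quantile normalization and under the other centring, DVU1045 to DVU1050, DVU1270 to DVU1275 and DVU2285 to DVU2293 stayed wholly called as higher. DVU0429 to DVU0436, DVU1280 to DVU1286 and DVU1810 to DVU1817 stayed wholly called as lower there, and the remaining runs did not. After loess no run stayed wholly called. The 6 genes from DVU1270 to DVU1275, 4 annotated for twitching motility or secretion and the last pair hypothetical, rose by 1.79 to 3.59, and all 49 assignments of arrays to cultures called each. The 6 genes from DVU1045 to DVU1050, which include genes for cytochrome c biogenesis, rose by 1.11 to 1.55. The 12 genes from DVU2995 to DVU3007, which include genes for sugar and polysaccharide enzymes, rose by 0.53 to 1.35. After loess 2, 3 and 5 genes of these runs lay below 0, and of the last run 1 after quantile normalization and 2 in the cDNA channel alone, where 3 of its 12 were called. All 49 assignments called 5 of the 6 genes from DVU1045 to DVU1050 and 6 of the 12 from DVU2995 to DVU3007.

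The authors' deposited table gave ratios from 1.43 to 4.24 for DVU1270 to DVU1275, all 6 at a q-value of 0. Its ratios were -0.19 to 0.67 for DVU1045 to DVU1050 and -0.43 to 0.66 for DVU2995 to DVU3007, with none at a q-value of 0. Of the genes not above background on any mutant array, 5 had a bound of at least 2-fold. The largest was dcrH (DVU3155), a chemotaxis sensor, at least 2.86-fold lower. Many others of these genes had bounds that showed no decrease, and all the bounds depend on the level set between the strains' tables. The authors' deposited table gives 0.33 for dcrH, not at a q-value of 0.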
